A study of Mus musculus with 10 samples.

How the data were processed

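Chromatin from bone marrow-derived mast cells was crosslinked with 1% formaldehyde, sonicated, immunoprecipitated with antibodies to H3K4me1 or H3K27ac and sequenced on an Ion Torrent Proton, per the labels' protocols. Peaks were called with MACS2 for each immunoprecipitate against its own input, with no pooling of replicates and a q-value limit of 0.001, per the file headers. The headers name version 2.1.1.20160309 for the 3 H3K27ac lists and 2.0.10.20130306 for the 2 H3K4me1 lists, while the submitters' processing notes name MACS2 2.0.10.20130306 and the mm9 build. The version of the caller therefore changes together with the mark. The aligner is not given in the sources used here.

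Each deposited list gives, per peak, its position and the authors' values. The signal is the pileup of extended tags at the summit, scaled by the caller from the larger library to the smaller, per the file headers. Undoing that scale gave whole tags within 0.05 for 100% of the peaks in each list. The fold enrichment is the authors' ratio of pileup to local background from the input, as deposited. The minus log10 p-value and −log10 q-value are also the authors' deposited values. Tags at the same position were kept once, per the file headers. This left 10457047 to 19513552 immunoprecipitate tags, of 12549448 to 23610254 in total, and 9433267 to 19265001 input tags. Estimated fragment lengths were 199, 210 and 201 bp for H3K27ac and 203 and 255 bp for H3K4me1. A fragment length of 255 bp, and narrow peak calling of marks that spread over kilobases, may both affect the length and number of peaks, which was not tested here. No counts per region were used here, so signal was not compared between lists outside a test of fold classes in the closing section, which was also run by ranks within each list, and a missing peak means only that the caller's limit was not passed.

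Positions are those of mm9 and are given counting from 1. The table of genes at hand was of GRCm38.p6, and on 9 of 20 chromosomes peaks lay past the last gene of that table, so it was not used for positions. Regions are therefore named by position, and promoters were not separated from enhancers. Sequence and gene annotation of mm9 were not used here.

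Peaks of a list were joined where they overlapped or touched. A consensus region was a joined region of the union of a mark's lists that held a peak of every list of the mark. Regions of the 2 marks were taken to overlap from 1 bp. A putative active enhancer was the joined stretch of overlapping H3K27ac and H3K4me1 consensus regions. Regions with only one of the marks were consensus regions with no peak of the other mark in any list. H3K27ac consensus regions were stitched across gaps of up to 12.5 kb, and clusters were ordered by the length covered. Shares have 95% Clopper-Pearson intervals. Random placement used 1000 seeded placements on the stretch from the first to the last peak of chromosomes 1 to 19 and X, and 200 under each alternative set of peaks. Densities per Mb used the same stretch. Exact tests were run over lists, and no correlation was computed over the 5 lists.

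Before the data were examined, the groups, the tests, the rule for the regions named and the alternatives were fixed. The rule named the 5 putative active enhancers and 5 H3K4me1 regions without H3K27ac with the best mean of ranks by fold within each list, the 3 such H3K27ac regions without H3K4me1, and the 5 clusters with the longest cover. The share of regions near transcription start sites, the comparison of 14 gene lists and the search for motifs were also fixed then, to be run only with an annotation or genome of the build, and were not run. Alternatives were a minus log10 q of at least 5 or 10, lists of equal size, an overlap of at least 0.5 of the shorter region, joining across 1000 bp, H3K27ac regions from at least 2 lists, each list left out in turn, another random placement, stitching across 5000 or 25000 bp, and pileup in place of fold. Alternatives and tests chosen later are named as such in the closing section.

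Replicate numbers 1 and 2 occur in both marks, but the titles number the 5 immunoprecipitates in a single series, so the numbers were not taken to pair the lists. No pair of lists was identical, since the highest Jaccard index was 0.588. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures from Matplotlib 3.10.9. The number of overlapping H3K27ac regions was checked with bedtools 2.31.1, which gave the same 7971. The code was tested on simulated data: for region sets of 6000 regions per mark, made with 40% shared, all 7 counts and shares were recovered, and for random placement without shared sites 1 of 50 simulations had p below 0.05, with a mean ratio of 0.953. In the latter both marks were spread evenly along the chromosomes. It therefore checks the code, not how the placement test behaves where peaks crowd in the same neighbourhoods.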

Results

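Histone H3 lysine 4 monomethylation (H3K4me1) and histone H3 lysine 27 acetylation (H3K27ac) were mapped by ChIP-seq in mouse bone marrow-derived mast cells, with the stated purpose of finding putative enhancers. H3K4me1 is a mark found at enhancers whether or not they are in use, and H3K27ac is found at active enhancers and promoters. The cells came from C57BL/6 mice 6 to 8 weeks old, were grown for 4 weeks with 20 ng/ml interleukin-3, and were over 99% positive for the IgE receptor and Kit. The 10 samples comprised 3 H3K27ac immunoprecipitates, 2 H3K4me1 immunoprecipitates and the 5 matching inputs, and each immunoprecipitate had its own list of peaks called against its own input. All cells were of 1 type and untreated, so the comparisons were between replicate lists and between marks. The labels did not state that the replicates were separate cultures or animals, so the p-values of tests over lists measure the spread between these samples, which may be technical. The caller used 16356587, 11413241 and 10457047 tags for H3K27ac replicates 1, 2 and 3, and 19513552 and 14685161 for H3K4me1 replicates 1 and 2. The inputs gave 10730453, 19265001 and 9433267 tags for H3K27ac and 14492927 and 12097147 for H3K4me1.

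The H3K4me1 lists held more and shorter peaks than the H3K27ac lists. The H3K27ac lists held 39837, 34035 and 30599 peaks, with median lengths of 493, 487 and 478 bp, and the H3K4me1 lists held 70726 and 59430 peaks, with median lengths of 356 and 437 bp. Covered sequence differed less between the marks: 30.7, 25.4 and 22.9 Mb for H3K27ac, and 34.1 and 34.2 Mb for H3K4me1. Within each mark the list made from the most immunoprecipitate tags held the most peaks. The caller scaled to the smaller of immunoprecipitate and input, and by that number the order differed for H3K27ac. The smaller library had 11413241 tags in replicate 2 and 10730453 in replicate 1, which held more peaks. Between the marks the smaller library also differed, with 14492927 and 12097147 tags for H3K4me1, above the 9433267 to 11413241 for H3K27ac. The lists of the 2 marks also came from different versions of the peak caller. The numbers of peaks of the marks therefore cannot be set against each other free of these differences.

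**Figure D1:**
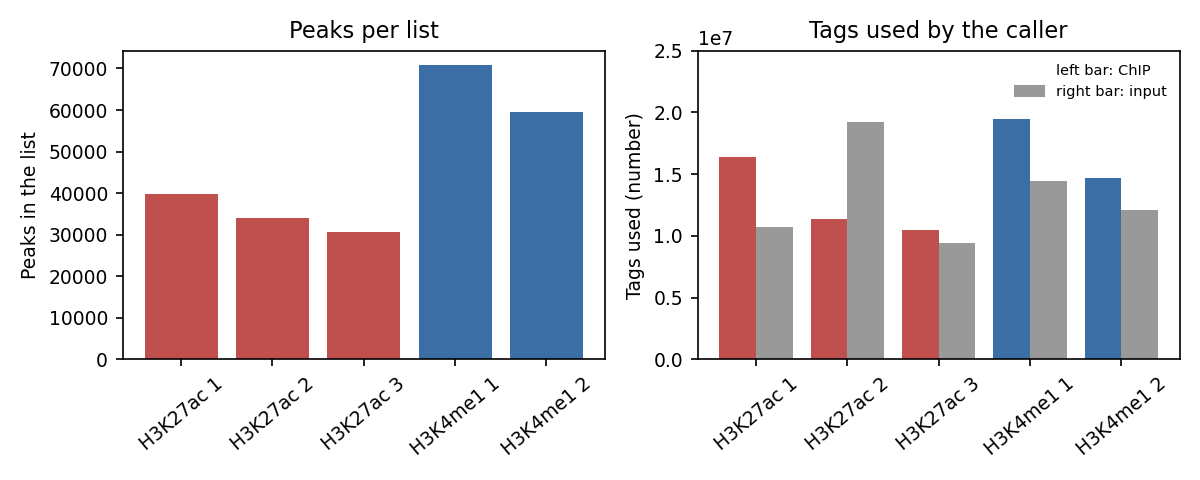
Number of peaks (left, y axis) and tags used by the caller (right, y axis, number of tags) for each list, named by mark and replicate on the x axis; H3K27ac is red, H3K4me1 is blue and the input of each list is grey. The 2 H3K4me1 lists held 59430 and 70726 peaks, above the 30599 to 39837 of the 3 H3K27ac lists.

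Most peaks of each list recurred in the other lists of its mark, and the recurring peaks were the higher ones. Of the peaks in H3K27ac replicates 1, 2 and 3, 56.5%, 68.5% and 75.7% overlapped a peak in both other lists of that mark, and of those in H3K4me1 replicates 1 and 2, 65.0% and 73.8% overlapped a peak in the other list. Peaks found in every list of the mark were higher than peaks found in no other: within H3K27ac replicate 1 the median fold enrichment over input was 10.6 against 6.17, within replicate 2 it was 7.72 against 5.32, and within replicate 3 it was 8.34 against 5.87. In H3K4me1 the medians were 6.82 against 6.01 in replicate 1 and 6.34 against 5.67 in replicate 2. The fold enrichment is the authors' own value for each peak and was compared only between peaks of a list, except in a test in the closing section that was also run by ranks within each list.

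The same lists were compared by the Jaccard index, the bases covered in both of a pair of lists divided by the bases covered in either. The 3 pairs of H3K27ac lists gave 0.566 to 0.588 and the H3K4me1 pair gave 0.468, while the 6 pairs of different marks gave 0.116 to 0.146. The mean within a mark was 0.551 ± 0.0564 (SD, n = 4 pairs) and between marks 0.128 ± 0.0126 (SD, n = 6 pairs), a difference of 0.423. The pairs share the 5 lists and are not independent. Each pair of different marks also differed in caller version, which cannot be told apart from the mark. In an exact two-sided permutation test over the 10 ways to call 3 of the 5 lists a mark, p = 0.1, the smallest value that the design allows. The highest difference of the other splits was 0.0643.

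**Figure D2:**
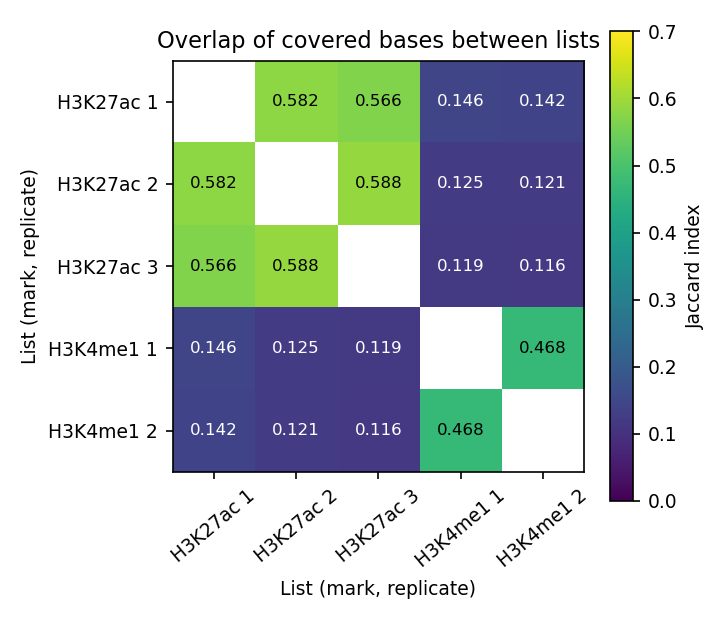
Jaccard index of covered bases for each pair of the 5 lists (rows and columns, mark and replicate), with the index as colour and number. Pairs of the same mark lie between 0.468 and 0.588, and pairs of different marks between 0.116 and 0.146.

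Regions that carried a peak in every list of a mark were taken as its consensus. H3K27ac had 19670 consensus regions covering 27.8 Mb, which was 45.5% (95% Clopper-Pearson interval 45.0 to 46.0) of the 43213 regions in its joined lists. H3K4me1 had 42329 consensus regions covering 32.7 Mb, which was 51.2% (50.9 to 51.6) of 82634. All such intervals cover counting error only. Presence in every list asks for 3 lists of H3K27ac but 2 of H3K4me1, so the 2 percentages are not of equal strictness. H3K27ac regions from at least 2 lists numbered 27973, and 30.1% of H3K4me1 consensus regions overlapped these. The number for H3K4me1 rests on 2 lists: with replicate 2 left out it was 70726. With only peaks of minus log10 q of at least 10, the numbers were 11316 for H3K27ac and 21732 for H3K4me1.

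The consensus sets of the marks overlapped at a minority of the regions of each. Of the H3K27ac consensus regions, 7971, or 40.5% (39.8 to 41.2), overlapped an H3K4me1 consensus region by at least 1 bp. Another 2474, or 12.6% (12.1 to 13.0), overlapped only H3K4me1 peaks outside the consensus, and the remaining 46.9% overlapped no H3K4me1 peak in any list. Of the H3K4me1 consensus regions, 10341, or 24.4% (24.0 to 24.8), overlapped an H3K27ac consensus region. Joining the overlapping regions gave 7587 putative active enhancers, that is, regions with both marks, with a median length of 1828 bp and a total of 17.8 Mb. Promoters were not removed from this number, because a gene annotation of the build was not used here. With only peaks of minus log10 q of at least 10, the number was 3468.

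The strongest regions with both marks, by the mean of their ranks by fold enrichment within each list, lay on chromosomes 1, 5, 18, 16 and 11 of the mm9 build. A region was ranked by its highest fold, so long regions with more peaks were favoured. Their lengths were 18909, 12490, 5728, 9606 and 10091 bp, all above the 90th percentile of 4439 bp for such regions, and the first was the longest. The region on chromosome 1 from 182345554 to 182364462 was 18909 bp long, with highest folds of 24.4, 19.6 and 19.6 in H3K27ac replicates 1, 2 and 3, and 17.5 and 16.6 in H3K4me1 replicates 1 and 2. The region on chromosome 5 from 75851230 to 75863719 reached 31.0, 18.3 and 19.9 for H3K27ac, and 14.2 and 13.3 for H3K4me1. The region on chromosome 18 from 60657803 to 60663530 reached 25.5, 18.4 and 24.5 for H3K27ac, and 15.3 and 11.99 for H3K4me1. Chromosome 16 from 92814622 to 92824227 held a region with 39.5, 21.7 and 24.3 for H3K27ac, and 17.7 and 10.6 for H3K4me1. Chromosome 11 from 115054419 to 115064509 held a region with 29.9, 24.1 and 24.6 for H3K27ac, and 12.3 and 14.3 for H3K4me1. What is annotated at these positions was not analysed here.

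Placing regions at random gave far less overlap than was measured. On chromosomes 1 to 19 and X, 7966 of 19638 H3K27ac consensus regions (40.6%) overlapped H3K4me1, against 682 ± 26.6 (SD of 1000 placements) when the regions were placed at random on their own chromosome, a ratio of 11.7. The one-sided permutation p was 0.001, the smallest that 1000 placements can give, and it measures the placement of regions, not the spread between samples. The ratio was 3.11 (p = 0.001, permutation) when each region was shifted by no more than 100 kb, a placement chosen after the data were seen that keeps the regional density of peaks.

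**Figure D3:**
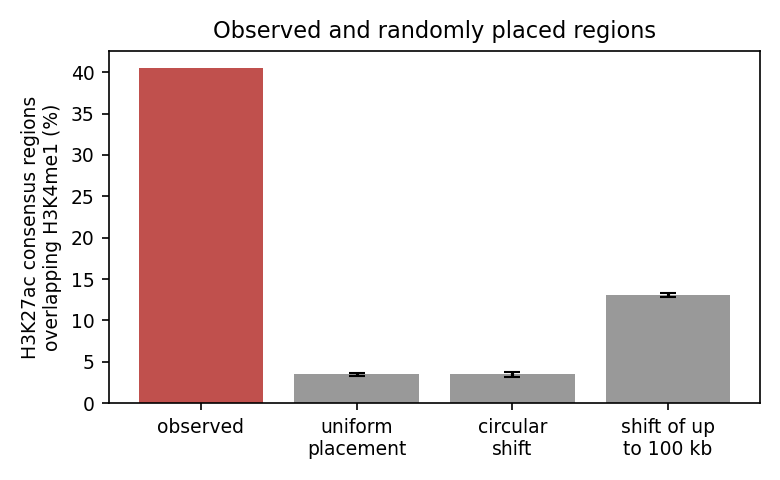
Share of H3K27ac consensus regions on chromosomes 1 to 19 and X that overlapped H3K4me1 consensus regions (y axis, percent) as observed (red) and as the mean over 1000 random placements of 3 kinds (grey, bars show the SD over placements). The observed share was 40.6%, and the 3 random means were 3.47%, 3.47% and 13.1%.

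Most H3K4me1 regions had no H3K27ac. Of the H3K4me1 consensus regions, 26102, or 61.7% (61.2 to 62.1), overlapped no H3K27ac peak in any list, and another 5886, or 13.9% (13.6 to 14.2), overlapped only H3K27ac peaks outside the consensus. H3K4me1 regions without H3K27ac were shorter than those with H3K27ac consensus, with median lengths of 571 and 711 bp. A longer region has more room to overlap, and no fixed window was used to separate this for H3K4me1. With H3K4me1 replicate 1 left out the number of regions without H3K27ac was 40090, with replicate 2 left out 48019, and with only peaks of minus log10 q of at least 10 it was 14094.

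Among H3K4me1 regions without H3K27ac, the region with the best mean rank was on chromosome 2 from 37787536 to 37788533, with highest folds of 19.5 in H3K4me1 replicate 1 and 17.0 in replicate 2, which ranked 20 and 15 in those lists. Next were chromosome 8 from 127390993 to 127391827, with folds of 19.6 and 14.9, and chromosome 7 from 134494754 to 134495430, with 18.0 and 14.0. The last of these 5 were chromosome 18 from 67600004 to 67600431, with 15.7 and 15.9, and chromosome 11 from 44270156 to 44270609, with 15.4 and 15.5. Their lengths were 998, 835, 677, 428 and 454 bp, of which 3 lay above the median of 571 bp for such regions and 2 below it.

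H3K27ac without H3K4me1 was also frequent. Of the H3K27ac consensus regions, 9225, or 46.9% (46.2 to 47.6), overlapped no H3K4me1 peak in any list, with a median length of 763 bp against 1398 bp for those that overlapped H3K4me1 consensus. The 3 with the best mean rank included some of the highest peaks of the lists. Chromosome 17 from 34256485 to 34261031 had folds of 46.7, 25.9 and 35.0 in replicates 1, 2 and 3, ranking 3, 7 and 2. Chromosome 5 from 135058622 to 135060797 had 45.8, 22.6 and 24.3, and chromosome 5 from 22938859 to 22942175 had 38.4, 20.7 and 23.7. With the peaks of a list joined across gaps of up to 1000 bp, the number without H3K4me1 was 5303, and with only peaks of minus log10 q of at least 10 it was 5908.

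Some H3K27ac regions had H3K4me1 beside but not across them. Of the 11699 H3K27ac consensus regions that overlapped no H3K4me1 consensus region, 24.4% (23.6 to 25.2) had such a region within 1000 bp of an edge and 49.0% (48.1 to 49.9) within 5000 bp. The same regions shifted by 10 kb had 17.3% and 36.7%, counting copies that landed on H3K4me1, and 8.00% and 29.6% with such copies left out. Within 500 bp the share was 15.0% (14.3 to 15.6), against 14.1% for all shifted copies and 4.40% for those that overlapped no H3K4me1. An H3K4me1 region lay within 2000 bp on both sides of 741 of them, or 6.33% (5.90 to 6.79), against 1.54% of shifted copies that overlapped none.

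Peaks that overlapped the other mark were longer and slightly higher than those that did not. In all 3 H3K27ac lists the median fold was higher with H3K4me1 than without: 8.12 against 7.82 in replicate 1, 6.84 against 6.69 in replicate 2 and 7.66 against 7.41 in replicate 3. The mean ratio was 1.03 ± 0.00830 (SD, n = 3 lists; exact sign test, two-sided p = 0.25, the smallest that 3 lists allow). In H3K4me1 the medians were 7.12 against 6.36 in replicate 1 and 6.60 against 6.02 in replicate 2, a mean ratio of 1.11 ± 0.0152 (SD, n = 2 lists; exact sign test, two-sided p = 0.5, the smallest that 2 lists allow). Median lengths were 625 against 446 bp, 611 against 442 bp and 600 against 434 bp in the H3K27ac lists, and 429 against 342 bp and 536 against 419 bp in the H3K4me1 lists. Longer peaks have more room to overlap, which was examined in the closing section for H3K27ac peaks only.

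Overlap with the other mark was most frequent among the highest peaks. In the lowest 4 of 5 equal classes of fold within an H3K27ac list, the mean share of peaks that overlapped H3K4me1 stayed between 33.9% and 34.4%, and in the highest class it was 41.0% ± 2.20 (SD, n = 3 lists). For H3K4me1 lists the share that overlapped H3K27ac was 16.4% ± 1.16 in the lowest class and 30.2% ± 0.885 in the highest (SD, n = 2 lists). No test was run across the classes.

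Most long H3K27ac regions carried H3K4me1. With the H3K27ac consensus regions divided into 4 equal classes by length, 21.0% (19.8 to 22.1) of the shortest class overlapped H3K4me1 consensus, and 67.5% (66.2 to 68.8) of the longest class did. Of the 533 regions of at least 5000 bp, 457 overlapped it, or 85.7% (82.5 to 88.6). A longer region also has more room to overlap.

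H3K27ac regions were stitched into clusters. Stitching neighbouring consensus regions gave 9688 clusters, of which 711 had at least 5 members and 78 had at least 10, and the most members in a cluster was 33. Clusters of randomly placed regions were not counted, so gathering beyond chance was not tested. A member need not be a separate element. With peaks joined across gaps of up to 1000 bp, H3K27ac consensus regions numbered 13769 in place of 19670, and clusters were not counted there. Members of larger clusters more often overlapped H3K4me1: 28.5% (27.3 to 29.8) of the 5073 regions that stood alone, 38.3% (37.3 to 39.3) of the 9692 regions in clusters of 2 to 4, and 57.3% (55.9 to 58.7) of the 4905 regions in clusters of at least 5. Median member lengths rose alongside, from 857 bp for regions that stood alone to 1292 bp in clusters of at least 5. The number of clusters with at least 5 members was 1088 with H3K27ac replicate 3 left out and 1290 with regions from at least 2 lists, and it was 239 with only peaks of minus log10 q of at least 10 and 374 with stitching across 5000 bp.

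The cluster with the longest H3K27ac cover lay on chromosome 15 from 78074048 to 78166852, where 18 consensus regions covered 73.3 of 92.8 kb and 14 of them overlapped H3K4me1. Chromosome 7 from 87513113 to 87621159 held 19 regions covering 71.5 kb, 16 of them with H3K4me1. Chromosome 17 from 35862776 to 35979305 held 33 regions covering 69.9 kb, 22 of them with H3K4me1. Chromosome 4 from 47260554 to 47337808 held 15 regions covering 58.0 kb, 12 with H3K4me1, and chromosome 13 from 43266209 to 43365443 held 24 regions covering 57.1 kb, 19 with H3K4me1.

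**Figure D4:**
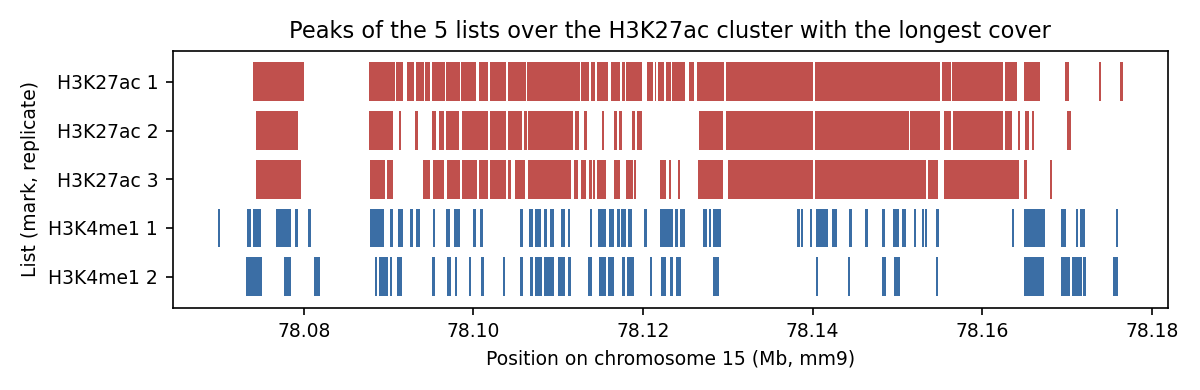
Peaks of the 5 lists (rows, mark and replicate; H3K27ac red, H3K4me1 blue) over the cluster on chromosome 15, with position in Mb of the mm9 build on the x axis; each bar is a peak drawn to scale. H3K27ac peaks of the 3 lists fill most of the span from 78074048 to 78166852, and H3K4me1 peaks are shorter and leave more of it uncovered.

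Chromosomes differed in how densely they were marked, a comparison made after the lists were seen. Chromosome 11 was the most densely marked of chromosomes 1 to 19 and X, with 15.0 H3K27ac and 34.4 H3K4me1 consensus regions per Mb, against medians over chromosomes 1 to 19 of 7.92 and 17.8. Chromosome X had the fewest, with 2.36 H3K27ac and 0.995 H3K4me1 regions per Mb. The density of peaks on X over that on chromosomes 1 to 19 was 0.311 ± 0.0176 (SD, n = 3) in H3K27ac lists and 0.0813 ± 0.0151 (SD, n = 2) in H3K4me1 lists, with p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 2 lists allow. Of the H3K27ac regions on X, 26 of 380, or 6.84% (4.52 to 9.86), overlapped H3K4me1 consensus, against 32.1% to 46.7% on each of chromosomes 1 to 19. With so few H3K4me1 regions on X, fewer overlaps could occur there. The share was not set against random placement chromosome by chromosome, so it does not show that the marks coincide less on X than their densities allow. Of the H3K4me1 regions on X, 29 of 160, or 18.1% (12.5 to 24.98), overlapped H3K27ac, against 22.2% to 28.4% on each of chromosomes 1 to 19.

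**Figure D5:**
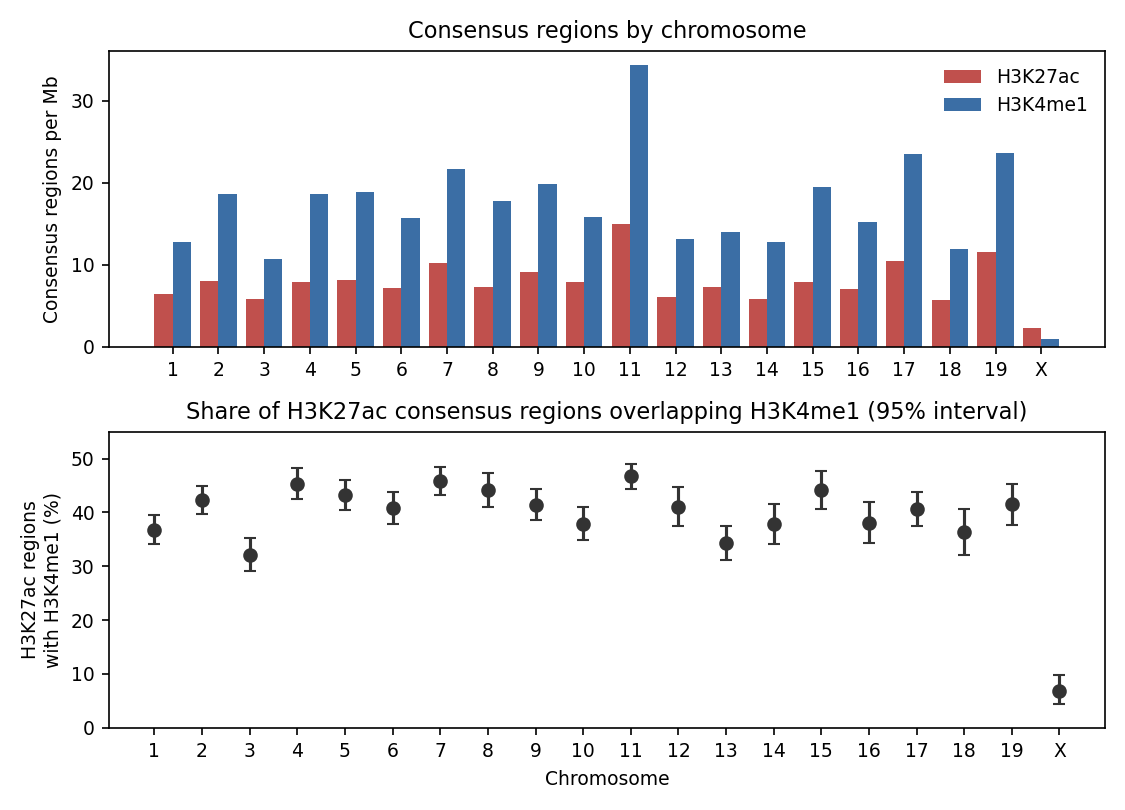
Top, consensus regions per Mb (y axis) of H3K27ac (red) and H3K4me1 (blue) on each chromosome (x axis). Bottom, share of H3K27ac consensus regions that overlapped H3K4me1 consensus regions (y axis, percent) on the same chromosomes, with 95% Clopper-Pearson intervals. Chromosome X is lowest in both, at 0.995 H3K4me1 regions per Mb and a share of 6.84%. The shares were not set against random placement on each chromosome.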

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

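Limiting peaks to a fold of at least 3, using chromosomes 1 to 19 alone and shifting regions by up to 100 kb were chosen after the data were seen, and the other alternatives before. A count was taken as kept within 1.5 times its value, a share within its 95% interval, a ratio of folds within 1 SD over lists, the ratio to random placement by direction and side of 0.05 and the Jaccard difference by its sign, whatever their size. By these unequal limits 100 of 144 values, over 12 results, were kept and 44 moved. Counts and shares have no direction to change, and the ratios and the Jaccard difference kept theirs. Some values were kept by construction. The consensus number of a mark cannot change when a list of the other mark is left out, nor can the clusters without an H3K4me1 list. The difference in Jaccard index within and between marks stayed above 0 and the ratio to random placement above 1 in each alternative run, but the ratio fell from 11.7 to 3.11 with shifts of up to 100 kb. Under the replicate block, with only pairs of different marks that share a number, the Jaccard difference was 0.418. The 2 such pairs averaged 0.133 and the 4 pairs with different numbers 0.125, so the numbers gave no hint of pairing beyond the spread of 0.0117 among the latter.

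With minus log10 q of at least 5, 39.1% of H3K27ac regions overlapped H3K4me1 and 23.8% of H3K4me1 regions overlapped H3K27ac, and the ratios of median folds with and without the other mark were 1.04 and 1.09. With at least 10 the shares were 31.4% and 21.6%, the ratios 1.07 and 1.03, the consensus numbers 11316 and 21732, the regions with both marks 3468, those with only H3K4me1 14094 and only H3K27ac 5908, and the clusters 239. These lower counts follow from fewer peaks, and the cause of the other shifts was not tested. Lists of equal size gave shares of 38.7% and 23.9% and a ratio of 1.09 for H3K4me1. Overlap by at least 0.5 of the shorter region gave 35.1% and 20.3%. Joining across 1000 bp gave 49.8% and 26.4%, with 5303 regions of H3K27ac only. H3K27ac regions from at least 2 lists gave 38.2% and 30.1%, with 1290 clusters. Stitching across 5000 bp gave 374 clusters. Pileup in place of fold gave ratios of 1.06 and 1.24. On chromosomes 1 to 19 the H3K27ac share was 41.2%.

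Leaving out each list in turn gave shares of 38.4% to 48.5% and 20.4% to 26.8%, 42329 to 70726 H3K4me1 regions, 26654 to 48019 of them without H3K27ac, 711 to 1088 clusters and ratios of 1.03 to 1.05 for H3K27ac. The highest H3K4me1 numbers came without an H3K4me1 list, since then a single list set the consensus. Depth limits how far an absent peak can be read, as lists from 10457047 to 19513552 immunoprecipitate tags differed in length. Shares near transcription start sites, gene lists and motifs, with their alternatives, were not run because an annotation and sequence of mm9 were not used here.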

Other observations

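The patterns in this part were noticed in the peak lists. The limits of 4 tests were set before their results were seen, and 4 tests, on H3K4me1 peaks with the pileup alone lowered, on X peaks by ranks within each list, on the background of H3K27ac peaks on X and without overlapping copies, were chosen only after the results were seen.

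Peaks on chromosome Y were few and differed between the marks. H3K27ac replicates 1, 2 and 3 had 4, 3 and 3 peaks there, and H3K4me1 replicates 1 and 2 had 0 and 0. A peak from 581394 to 582138 in replicate 1, with a fold of 15.2, had an overlapping peak in each other H3K27ac list, with folds of 10.1 and 11.7. The sex of the mice is not given in the labels used here.

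Some peaks had a high pileup and a low fold, because the input was high there too. Peaks with a pileup over 60 and a fold under 3 numbered 3, 23 and 2 in the H3K27ac lists and 24 and 31 in the H3K4me1 lists. In H3K27ac replicate 2, 16 of the 23 were on chromosome 9 and 3 were on chromosome 2 between 98502379 and 98507500, where the pileup reached 420 at folds of 1.33 to 1.71. In the H3K4me1 lists, 9 and 16 such peaks lay on chromosome 11, between 3023874 and 3047096 in replicate 1 and between 3023814 and 3069066 in replicate 2. Without any peak of fold under 3, the number of regions with both marks was 7518.

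Chromosome X carried few peaks, fewest in the H3K4me1 lists, where the density was 0.0919 and 0.0706 of that on chromosomes 1 to 19. With the autosomal signal and background lowered to 0.5, as for a chromosome at lower dose with as many sites per Mb, 73.7% to 79.9% of autosomal H3K4me1 peaks still passed the weakest called p, up to 10.4 times the X density, and with the pileup alone lowered at least 5.12 times it, so a dose of 0.5 is argued against as the whole cause there. In the H3K27ac lists the X density was 0.481, 0.547 and 0.469 of the surviving share with both lowered, past the limit of 1.5 times. A dose of 0.5 in both is thus argued against as the whole cause there but may be part of it. A local background above the genome-wide one was found for 27.03% (24.0 to 30.2), 27.6% (24.4 to 31.1) and 21.1% (17.9 to 24.7) of X peaks. Of the survivors with both lowered, 19.6%, 27.1% and 18.6% had it, the first below its interval. An input that is not lower is argued against in these lists. Survivors with the pileup alone lowered (1.71, 1.37 and 1.62 times the X density) lay at least 47.9 percentage points above the X peaks in that share. In the H3K4me1 lists that share was 69.9% (65.3 to 74.2) and 52.3% (46.3 to 58.3) of X peaks, with no limit set. It lay between the 37.8% and 29.1% of survivors with both lowered and the 90.6% and 86.6% with the pileup alone lowered. Weaker peaks in the H3K4me1 lists are argued against as the whole cause, since the H3K4me1 share of peaks on X was at most 0.377 of the H3K27ac share in 3 classes of fold and, as folds of lists from different inputs share no scale, also by ranks within each list, where the strongest of 5 equal classes of H3K4me1 peaks had 0.269% and 0.177% on X, at most 0.272 of the lowest share in any class of an H3K27ac list. Fewer sites on X, the caller version and differences between the mice stay open, so the pattern may be biological or technical, and no biological explanation was tested.

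H3K27ac regions that overlapped H3K4me1 were longer. In a fixed window of 500 bp around each H3K27ac summit, the share with H3K4me1 was 5.83, 5.56 and 4.61 percentage points higher in the longest than in the shortest of 4 equal classes of peaks by length in replicates 1, 2 and 3. This lies near the limit of 5 set beforehand for a length effect alone, while overlap of the whole of the same peaks differed by 24.9, 24.6 and 23.6 percentage points, a comparison added after the result was seen. Room to overlap may therefore account for much of the difference between these peaks, and the remainder cannot be told apart from it at these values. The gap between 21.0% and 67.5% for consensus regions was not tested in a fixed window.

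H3K4me1 also lay beside H3K27ac regions that it did not overlap. The share with H3K4me1 within 1000 bp was 24.4%, which was 1.41 times that of the same regions shifted by 10 kb, between the limits of 1.2 and 1.5 set beforehand, and within 500 bp the ratio was 1.06. That control counts shifted copies that land on H3K4me1, which the regions themselves cannot do, and against copies that overlapped none the ratios were 3.05 and 3.40. The test set beforehand did not decide, and the control with copies that overlapped none was chosen only after its result was seen. By that later control alone, crowding of the marks over distances of 10 kb or more is argued against as the whole cause. Crowding over shorter distances stays open. A candidate explanation is H3K4me1 flanking an H3K27ac center, which was not tested by any annotation.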
